A study of Mus musculus with 16 samples.

How the data were processed

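RNA was sequenced from P14 CD8+ T cells, which carry a transgenic T cell receptor against a glycoprotein peptide of lymphocytic choriomeningitis virus (LCMV). The cells came from C57BL/6 mice and were sorted into 8 groups by surface markers, with 2 libraries per group. The labels give TRIzol for the RNA and a PrepX kit for the libraries. They do not say whether the libraries of a group came from separate animals. The labels trace 8 of the libraries (IEL_Trm, tTem, convTem and Tcm) to 1 earlier deposit and 6 (MP, TE and naive) to another. Tem alone has no earlier deposit named.

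The deposited table holds 1 expression signal per gene and library. Per the labels, the authors named TopHat, HTSeq and DESeq as their tools and mm10 as the genome build, without versions. The annotation release, the strand setting and any filter are not given in the sources used here, so antisense and overlapping transcripts cannot be separated. Each deposited signal equals a read count divided by 1 factor per library, plus 1. After subtraction of that 1, 100% of the values in every library lay within 0.01 steps of a whole multiple of 1 step. Dividing by that step gave the reads behind each value, called recovered reads, and hence the depth, which ran from 2339149 reads (naive library 2) to 7401839 (IEL_Trm library 1). Of the 16 columns, 14 carry names that match their sample titles. The other 2 are headed LLTE, and they were taken as tTem, the only pair of samples without a column of its own name. No mapping was checked by genotype. The table has 44554 entries, in which 38 symbols stand on several lines (78 lines in all), each tested on its own.

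The values after subtraction of 1 are called normalized reads below. Genes with at least 10 normalized reads in at least 2 libraries were tested (13549 genes). The log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3, using 1 mean per group over all 16 libraries (8 residual degrees of freedom) and a variance trend on the mean level. Each comparison was a contrast of group means, tested on both sides, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. The IEL_Trm group was set against the mean of tTem, Tem and Tcm, each with equal weight. The count models planned for read counts were not run, since the table holds normalized values. Voom on the recovered reads, added after the data were seen, stands beside the main test.

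Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, for lists with at least 5 measured members. Values were adjusted over the lists within each comparison. Of 6 genes taken as sort markers, 5 are also members of another list. Cd69 is among the 6, although no label names CD69 as sorted on. List tests between groups sorted on the other markers therefore include genes whose direction the gate set, and no list was tested without such genes. The day 7 signatures, genes past the threshold in TE against MP with a log2 change of at least 1 in either direction, were tested with camera in the other comparisons. The 31 lists, the comparisons, the tests and most alternatives were chosen before the data were examined. The genes named in each comparison follow a rule fixed at the same time. Of genes past the threshold, without overlap between the libraries of the groups compared and with a mean of at least 100 normalized reads in the higher group, the 10 with the largest change in each direction are named, and unnamed models, small RNAs and antigen receptor segments are left out. Those of the difference between days are named in part with the closing interpretation. Up to 4 members of each list with the lowest adjusted p, and 6 genes taken as sort markers, complete the set. The text draws on these without naming all of them. A result for 1 of these genes is not reported here.

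Gene positions, exonic length and GC content came from GENCODE M21 on GRCm38 (mm10), in which 13218 of the 13549 symbols tested were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A fold against a group with no reads in either library is given only as a lower bound, computed from 3 reads in each library. Such bounds and the depths cover counting error alone, since reads without molecular identifiers are not independent molecules. Spread between replicates was well above counting error. The chi-square per degree of freedom between the libraries of a group ran from 6.95 (Tcm) to 21.7 (naive). Abundant features weigh most in it. In naive libraries 1 and 2, mt-Co1 was at 158176 and 39876, and the ribosomal RNA locus CT010467.1 took 4.79% and 11.8% of reads. The median absolute log2 difference between the libraries of a group ran from 0.281 (TE) to 0.360 (naive).

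The procedure was tested on simulated data built from these values with 50 changed genes at each size. All groups had the same mean except for the changed genes in 1 group, and genes of like expression shared 1 spread. The rates below hold for that simpler case. For tTem against Tem it recovered 4% of genes changed 1.5-fold, 50% at 2-fold, 84% at 4-fold and 100% at 8-fold, and 4.8% of its calls were false. For IEL_Trm against spleen memory, recovery was 20% at 1.5-fold, 66% at 2-fold and 96% at 4-fold. For the difference between the day 55 and day 7 contrasts it was 0% at 1.5-fold, 14% at 2-fold and 92% at 8-fold. A change of 1.5-fold was therefore more often missed than found in all 3.

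Settings varied by plan were the pseudocount (0.5 or 8), no filter on low values or a filter at 50, trimmed-mean scaling, the replicate number as a block, a fit on the groups compared alone or on 1 earlier deposit, a minimum log2 change of 1, an estimated correlation for the lists, no minimum change in the day 7 signatures, convTem in place of Tem for those signatures, and leaving out each library. Added after seeing the data were limma's voom on the recovered reads, autosomal genes only, convTem in place of Tem in the difference between days, scaling without features of the ribosomal RNA locus and the mitochondrial genome, removal of a trend on gene length and GC content, and the replicate number as a block in the day 7 and naive libraries alone. Sequence reads were not used here.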

Results

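The data are 16 RNA-seq libraries of P14 CD8+ T cells, 2 for each of 8 sorted groups, from mice infected with LCMV or from uninfected T cells of the same receptor. Spleen groups from day 55 were tTem (CD127lo CD62Llo), Tem (CD127hi CD62Llo), Tcm (CD127hi CD62Lhi) and convTem, which was gated on low CD62L alone. IEL_Trm cells of day 55 are labelled CD103hi CD62Lhi and came from the epithelium of the small intestine. Day 7 gave TE (CD127lo KLRG1hi) and MP (CD127hi KLRG1lo), and naive cells were CD62Lhi CD44lo. Depth was 7401839 and 6700995 recovered reads in IEL_Trm, 6211693 and 6790513 in tTem, 4808489 and 6233688 in convTem, 5801368 and 5517636 in Tcm, and 4673983 and 5339913 in Tem. It was 6077856 and 5983730.0 in MP, 6843349 and 4490541 in TE, and 3680005 and 2339149 in naive cells. Values are normalised read counts as mean ± SD (n = 2), changes are log2 differences ± SE, and p-values are from limma, adjusted by the Benjamini-Hochberg method. A pair of values in brackets after a gene list is its adjusted p with the preset and with an estimated correlation. Nothing in the labels says that libraries came from separate animals, so the p-values measure only the spread between these libraries.

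Transcripts of sort markers were compared first, as a check of the labels. Il7r, which encodes CD127 (chromosome 15, 9505788 to 9530176 on GRCm38), was at 178 ± 17.3 in tTem and 43.7 ± 5.09 in TE. It was at 1301 ± 6.36 in convTem, 1505 ± 349 in MP, 2032 ± 46.4 in Tem and 2268 ± 27.6 in Tcm. Itgae, which encodes CD103 (chromosome 11, 73090583 to 73147446), was at 5176 ± 446 in IEL_Trm and 28.1 ± 2.69 in tTem. Klrg1 was at 3578 ± 181 in TE and 56.5 ± 5.64 in MP. Cd44 was at 55.7 ± 16.0 in naive cells and 923 ± 57.9 in Tcm. Cd69 was at 4982 ± 965 in IEL_Trm, but no label names CD69 as sorted on, so its level checks no label.

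**Figure D1:**
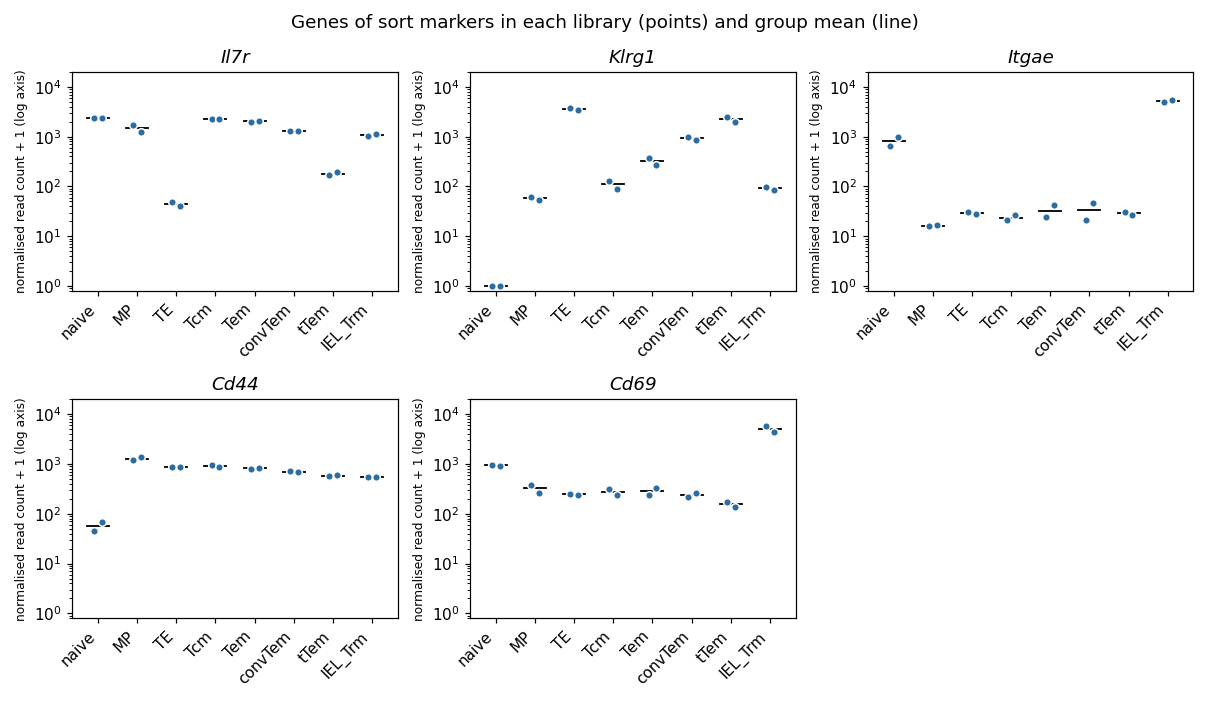
Normalised read count plus 1 (log axis) of 5 genes taken as sort markers in the 8 groups. Points are libraries and lines are group means, with Il7r at 178 in tTem and 2032 in Tem.

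The comparison of tTem with Tem asked what separates CD127lo from CD127hi cells among CD62Llo memory cells. The Tem libraries also differ from those of tTem in that no earlier deposit is named for them. Gzma, a granzyme gene (chromosome 13, 113093825 to 113100981), was at 2899 ± 125 in tTem and 149.8 ± 79.4 in Tem (4.37 ± 0.30, adjusted p = 6.65e-08). Cx3cr1, which encodes the fractalkine receptor (chromosome 9, 119901616 to 120069879), was at 4179 ± 253 against 401 ± 10.7 (3.38 ± 0.22, adjusted p = 3.21e-08). Myc, a growth regulator (chromosome 15, 61985391 to 61990374), fell from 730.0 ± 41.9 in Tem to 38.4 ± 19.0 in tTem (-4.30 ± 0.26, adjusted p = 1.63e-08).

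Of 25 measured genes of terminal effector cells, 15 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 1.33e-14). Zeb2, a repressor active in effector cells (chromosome 2, 44983632 to 45117395), was at 2054 ± 48.2 in tTem and rose by 3.47 ± 0.35. Klrg1 rose by 2.82 ± 0.23, while Itgax fell by 2.30. Among natural killer lectin-like receptors, 8 of 13 rose and none fell (9 adjusted over the list alone, adjusted p = 1.82e-09). They included Klre1 at 269 ± 45.6 against 17.8 ± 9.63, though members of this family share reads and single values are uncertain. Of 20 cytotoxic genes, 6 rose and 2 fell (7 and 4 adjusted over the list alone, adjusted p = 0.0383), which did not pass with adjusted p = 0.251 with an estimated correlation. Prf1, for perforin, rose by 1.35 ± 0.12 and Gzmb by 0.97 ± 0.13.

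Lymphoid homing genes fell in 8 of 18 cases and rose in 2 (10 and 2 adjusted over the list alone, adjusted p = 7.89e-07). Ccr7, which guides cells into lymph nodes (chromosome 11, 99144196 to 99155077), was at 71.9 ± 4.95 in tTem and fell by 3.16 on the log2 scale. Cxcr3 was at 734 ± 93.0 against 4167 ± 46.8, and As3mt rose by 2.48 ± 0.19. Of 20 regulators tied to memory and naive cells, 6 fell and 1 rose (7 and 2 adjusted over the list alone, adjusted p = 0.00539). Id3 was at 0.366 ± 0.518 against 42.5 ± 14.6, Bcl2 fell by 1.34 ± 0.15, and Tcf7 was at 969.8 ± 94.6 against 1366 ± 3.78 (adjusted p = 0.0328). Ribosomal protein genes fell in 73 of 84 cases (77 adjusted over the list alone) with a median change of -0.94 (adjusted p = 5.09e-74). Rps15a was at 1043 ± 21.0 against 3005 ± 121, and values of single ribosomal genes are uncertain because of processed pseudogenes.

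Other lists passed with the preset correlation only. Tissue residency genes fell in 10 of 30 cases and rose in 3 (14 and 5 adjusted over the list alone, adjusted p = 0.001), with adjusted p = 0.101 with an estimated correlation. Inhibitory receptors fell in 5 of 13 cases and rose in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.001), with adjusted p = 0.0754 with an estimated correlation. Tigit was at 27.3 ± 5.99 against 130.2 ± 37.6. Interferon-stimulated genes fell in 6 of 30 cases (9 down and 1 up adjusted over the list alone, adjusted p = 0.00871), with adjusted p = 0.131 with an estimated correlation. Of 10 B cell markers, 2 fell (3 adjusted over the list alone, adjusted p = 0.0383), with adjusted p = 0.118 with an estimated correlation. Cd79b was at 17.6 ± 16.7 in tTem and 110.2 ± 13.2 in Tem, and Ighm at 353 ± 1.98 and 1096 ± 11.8. Chemokine receptors (0.0383 and 0.259) and oxidative phosphorylation genes (0.0216 and 0.394) passed downward, with the preset correlation alone. After removal of a trend on gene length and GC content, oxidative phosphorylation genes no longer passed (camera, adjusted p = 0.252). Their median change went from -0.116 to -0.020.

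The other genes with the largest changes were Srcin1 (248 ± 19.4 against 9.20 ± 7.37), Cmklr1, Gsn, S1pr5 and Ccl9 among those that rose. S1pr5, a receptor for exit from tissue, was at 4477 ± 174 against 619.8 ± 168 (adjusted p = 0.0297). Its call ended whichever of the 4 libraries was left out, with adjusted p up to 0.175. The calls of Ccl9 (up to 0.149), Cmklr1 (up to 0.190), Gsn (0.0558) and Xcl1 (0.0538) ended without some of them. Among those that fell, Rgs10 was at 9.59 ± 13.6 against 336 ± 40.8, Gas7 at 1.37 ± 0.131 against 171 ± 27.9, and Asb2 at 14.6 ± 9.23 against 346 ± 31.8. Pak6 was at 1.83 ± 2.59 against 139 ± 2.99, and Atp8a2, P2rx7 and Rflnb fell by 4.69, 4.44 and 3.89 on the log2 scale. Socs3, an inhibitor of cytokine signals, was at 7.55 ± 7.96 against 141 ± 18.9. In all, 1023 of 13549 genes differed, 436 higher and 587 lower. The count was 193 in a fit of these groups alone, 566 with a minimum log2 change of 1, 526 without tTem library 1 or Tem library 1, and 640.0 without Tem library 2.

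**Figure D2:**
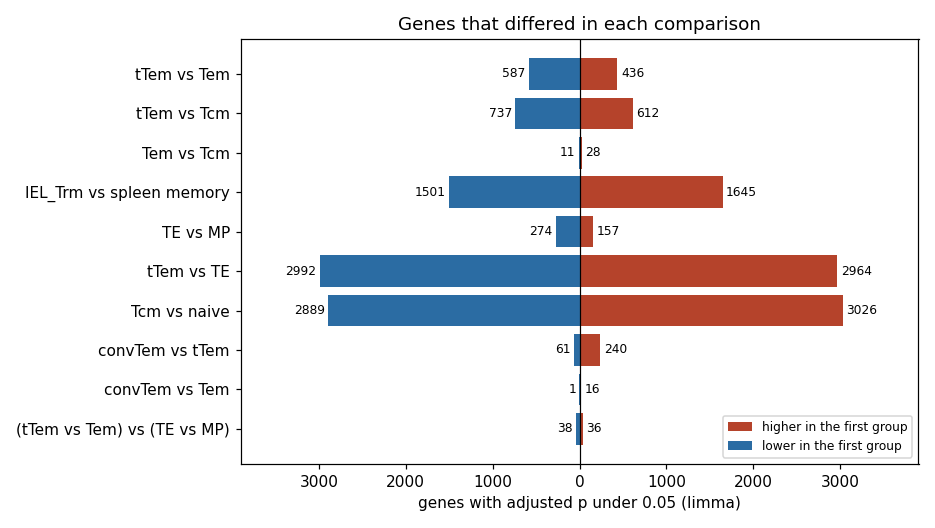
Number of genes past the threshold in each comparison, split into higher and lower in the group named first. The bars run from 17 genes (convTem against Tem) to 5956 (tTem against TE).

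The comparison of tTem with Tcm placed the CD127lo cells against memory cells sorted as CD127hi CD62Lhi. Gzma was at 2899 ± 125 in tTem and 4.01 ± 1.03 in Tcm (9.19 ± 0.30, adjusted p = 3.47e-12). Cx3cr1 rose by 6.03 ± 0.22 and Zeb2 by 4.63 ± 0.35. S1pr5 was at 4477 ± 174 against 174 ± 33.2. Ccr7 fell by 4.67 on the log2 scale.

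Terminal effector genes rose in 19 of 25 cases and fell in 1 (21 and 1 adjusted over the list alone, adjusted p = 4.2e-22), among them Lgals3 at 873 ± 122 against 113 ± 7.24. Natural killer lectin-like receptors rose in 7 of 13 cases (11 adjusted over the list alone, adjusted p = 1.63e-12), with Klrb1c at 1051 ± 103 against 69.3 ± 28.6. Of 20 cytotoxic genes, 7 rose and 3 fell (9 and 4 adjusted over the list alone, adjusted p = 0.000236), with adjusted p = 0.056 with an estimated correlation. Gzmb was at 2404 ± 265 against 305 ± 8.17. Homing genes fell in 10 of 18 cases and rose in 1 (11 and 2 adjusted over the list alone, adjusted p = 1.34e-09). They included Dapl1, Treml2 and Actn1, which were at 0.732 ± 1.04, 2.56 ± 3.62 and 2.56 ± 3.62 in tTem and at 147 ± 24.6, 197 ± 42.0 and 132 ± 20.4 in Tcm. Memory regulators fell in 7 of 20 cases (7 down and 3 up adjusted over the list alone, adjusted p = 0.00118). Ribosomal protein genes fell in 76 of 84 (78 adjusted over the list alone, adjusted p = 1.41e-80, adjusted p = 0.00895 with an estimated correlation). Cell cycle genes passed downward at adjusted p = 0.027, with adjusted p = 0.49 with an estimated correlation. Replication-dependent histone genes (0.038 and 0.324) passed upward, and oxidative phosphorylation genes (0.031 and 0.539) passed downward, with the preset correlation alone. Neither list passed with trimmed-mean scaling (camera, adjusted p = 0.0507 for each). After removal of a trend on gene length and GC content, the median of the oxidative phosphorylation genes went from -0.116 to -0.0075 (camera, adjusted p = 0.383).

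Cxcr5, the receptor that draws cells to B cell follicles, was at 4.84 ± 5.81 in tTem and 156 ± 14.4 in Tcm. Nsg2, Aff3 and Tlr1 were at 3.70 ± 1.09, 1.42 ± 1.10 and 2.56 ± 3.62 in tTem, against 292 ± 52.8, 137 ± 15.6 and 139 ± 33.3 in Tcm. Havcr2 and Lag3, both inhibitory receptors, were at 24.4 ± 11.7 and 50.9 ± 27.5 in tTem, against 1.63 ± 1.18 and 7.73 ± 5.33 in Tcm. As a list, inhibitory receptors did not pass, with 4 of 13 higher and 4 lower (camera, adjusted p = 0.962). Cd79b was at 17.6 ± 16.7 against 129 ± 30.7. Klre1, Srcin1, Cmklr1, Klrg1 and Ccl9 also rose, by 3.93 (Ccl9) to 6.81 (Klre1) on the log2 scale, and Rgs10 and Gas7 fell by 6.87 and 6.68. Of all genes, 612 were higher and 737 lower (1349 in all). Voom gave 821 higher and 764 lower, so which direction held more genes depended on the method. The count was 416 in a fit of these groups alone, 808 with a minimum log2 change of 1, 796 without tTem library 1, 795 without Tcm library 1 and 736 without Tcm library 2.

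The comparison of Tem with Tcm set CD62Llo against CD62Lhi cells among CD127hi cells. An earlier deposit is named for the Tcm libraries and none for those of Tem, so gate and library origin change together. Few genes differed. Ckb, a creatine kinase (chromosome 12, 111669361 to 111672338), was at 142 ± 31.7 in Tem and 3.19 ± 2.19 in Tcm (5.18 ± 0.53, adjusted p = 6.45e-05). Gzma was at 149.8 ± 79.4 against 4.01 ± 1.03 and Gzmb at 1225 ± 107 against 305 ± 8.17. Cx3cr1 rose by 2.65 ± 0.22 and Klrb1c by 2.53 ± 0.28. Ccr7 fell by 1.51 on the log2 scale.

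Terminal effector genes rose in 6 of 25 cases (10 up and 1 down adjusted over the list alone, adjusted p = 7.83e-13), and cytotoxic genes in 2 of 20 (3 and 1 adjusted over the list alone, adjusted p = 1.22e-06). Residency genes rose in 3 of 30 cases and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 5.45e-11), with Hic1 at 52.4 ± 10.5 against 3.56 ± 5.03. Inhibitory receptors rose in 3 of 13 cases (5 adjusted over the list alone, adjusted p = 7.94e-08), with Lag3 at 69.1 ± 0.546 against 7.73 ± 5.33 and Cd160 at 1099 ± 159.8 against 511 ± 3.98. Homing genes fell in 4 of 18 cases (6 adjusted over the list alone, adjusted p = 8.19e-06). No ribosomal protein gene passed alone, although the list passed downward (adjusted p = 3.11e-13, adjusted p = 0.229 with an estimated correlation). Natural killer lectin-like receptors rose in 2 of 13 cases (3 adjusted over the list alone, adjusted p = 5.28e-05). Myeloid markers (0.0297 and 0.107), CD4 T cell markers (0.0411 and 0.25) and natural killer cell markers (0.0282 and 0.102) passed upward, and genes of circulating cells (0.0282 and 0.13), cytokine receptors (0.0227 and 0.102) and cell cycle genes (0.0282 and 0.394) passed downward, with the preset correlation alone. Asb2, P2rx7, Bhlhe40, Klrg1 and Coro2a rose, and Dapl1, Il6ra and Ap1b1 fell. Each of these 8 calls ended without at least 1 library, with adjusted p up to 0.299 for Ap1b1. In all, 28 genes were higher and 11 lower (39 genes). In a fit of these groups alone limma called 0 genes, with 1122 at an unadjusted p under 0.05, and voom on all libraries called 35. The count was 18 without Tcm library 2, 24 without Tem library 1 and 23 without Tem library 2 (11 higher and 12 lower).

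The convTem group, gated on low CD62L without CD127, was compared with its CD127lo and CD127hi counterparts. Against tTem, Il7r rose by 2.87 ± 0.15 and Myc by 3.55 ± 0.26, with Myc at 434 ± 71.0 in convTem. Plac8 was at 989 ± 22.1 against 211 ± 44.0 and Cxcr3 at 3179 ± 576 against 734 ± 93.0. Gzma was at 858 ± 39.1 against 2899 ± 125 and Cx3cr1 at 1500.0 ± 13.1 against 4179 ± 253. Rgs10, Rflnb, Asb2, Ccr7, Bicdl1 and Art2b also rose, by 2.11 (Art2b) to 5.27 (Rgs10) on the log2 scale, and Eps8l1, Zeb2, Tef, Klrg1, Apobec2, As3mt, Fry and Cep68 fell, by 1.01 (Cep68) to 1.79 (Eps8l1). With 1 library left out in turn, 11 of the 20 calls named by rule in this comparison ended at least once, namely those of Gzma, Bicdl1, Art2b and the 8 genes just named as lower, with adjusted p up to 0.364 for Bicdl1. Ribosomal protein genes rose in 54 of 84 cases (71 adjusted over the list alone, median 0.64, adjusted p = 1.01e-64, adjusted p = 0.0175 with an estimated correlation). Homing genes rose in 7 of 18 and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 1.06e-08). Terminal effector genes fell in 6 of 25 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 4.25e-08). B cell markers rose in 2 of 10 cases (2 adjusted over the list alone, adjusted p = 0.0115), with adjusted p = 0.0772 with an estimated correlation. Memory regulators rose in 4 of 20 cases (5 adjusted over the list alone, adjusted p = 0.000225). Natural killer lectin-like receptors fell in 2 of 13 (6 adjusted over the list alone, adjusted p = 7.35e-05). Residency genes (0.00602 and 0.145), inhibitory receptors (0.00681 and 0.123) and chemokine receptors (0.0128 and 0.18) passed upward, and cholesterol synthesis genes (0.0308 and 0.417) passed downward, with the preset correlation alone. Among 301 genes, 240.0 were higher and 61 lower in convTem. Limma called 0 genes in a fit of these groups alone, with 1589 at an unadjusted p under 0.05 (voom on all libraries called 384), and 164 genes had a log2 change of at least 1. The count was 134 without tTem library 1, 92 without convTem library 1 and 115 without convTem library 2, and Gzma passed with each library left out except convTem library 1 (adjusted p = 0.0528).

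Against Tem, 16 genes were higher in convTem and 1 was lower (17 genes). Gzma rose by 2.62 ± 0.30, Cx3cr1 by 1.90 ± 0.22, Zeb2 by 1.98 ± 0.35 and Klrg1 by 1.54 ± 0.23. As3mt, Borcs7 and Prf1 rose by 1.34, 1.75 and 0.64. Cd200r1, which encodes an inhibitory receptor, fell from 24.2 ± 1.78 to 1.10 ± 1.55 (named as the single gene that fell, chosen after its values were seen). Terminal effector genes rose in 4 of 25 cases (8 adjusted over the list alone, adjusted p = 1.87e-13). Natural killer lectin-like receptors rose in 1 of 13 cases (6 adjusted over the list alone, adjusted p = 5.4e-08). Cytotoxic genes (0.0228 and 0.264), genes of circulating cells (0.0199 and 0.171) and immediate-early and heat-shock genes (0.0387 and 0.493) passed upward, and inhibitory receptors (0.0366 and 0.264), interferon-stimulated genes (0.0228 and 0.264) and ribosomal protein genes (1.68e-30 and 0.171) passed downward, with the preset correlation alone. After removal of a trend on gene length and GC content, immediate-early and heat-shock genes no longer passed (camera, adjusted p = 0.0594). Their median change went from 0.169 to 0.0910. In a fit of these groups alone limma called 0 genes, with 1019 at an unadjusted p under 0.05, and voom on all libraries called 18. The count was 2 without either convTem library, 7 without Tem library 1 and 4 without Tem library 2, and only Gzma and Cx3cr1 of the genes named by rule passed each time.

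IEL_Trm cells were compared with the mean of tTem, Tem and Tcm to find what marks resident cells of the gut. Itgae, whose product CD103 was sorted on, was at 5176 ± 446, against 22.6 ± 4.02 to 31.8 ± 12.6 in the spleen groups. Its change (7.54 ± 0.30, adjusted p = 4.27e-12) was set by the gate and is a check of the labels. Gzmb reached 18467 ± 2827 and Cd69, which holds cells in tissue, 4982 ± 965. S1pr1, the receptor for exit into blood and lymph (chromosome 3, 115710433 to 115715072), was at 31.0 ± 3.62 against 1149 ± 43.4 to 1835 ± 70.8 (-5.51 ± 0.13, adjusted p = 6.66e-15). Cx3cr1 fell by 5.65 and Klf2 by 3.28 on the log2 scale.

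All 30 measured residency genes rose (30 adjusted over the list alone, adjusted p = 9.36e-36). Ccr9, a gut homing receptor, was at 2779.7 ± 85.7 and Ctla4 at 1717 ± 121. Genes of circulating cells fell in 18 of 21 cases and rose in 1 (18 and 1 adjusted over the list alone, adjusted p = 2.66e-25), and homing genes fell in 11 of 18 and rose in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.98e-08). Cytotoxic genes rose in 15 of 20 cases and fell in 2 (16 and 2 adjusted over the list alone, adjusted p = 1.02e-12). Gzma was at 9368 ± 674 and Ccl4 at 11478 ± 177, whereas Gzmm fell to 25.8 ± 10.2. Inhibitory receptors rose in 11 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 1.46e-12), with Cd160 at 5931 ± 58.2, Tigit at 1424 ± 25.7 and Pdcd1 at 1081 ± 199. Terminal effector genes fell in 16 of 25 cases and rose in 5 (16 and 6 adjusted over the list alone, adjusted p = 4e-05), with Lgals1 at 385 ± 142 against 4104 ± 655 to 11382 ± 193. Natural killer lectin-like receptors fell in 6 of 13 cases (6 adjusted over the list alone, adjusted p = 0.000142). Fatty acid genes (0.00127 and 0.12) and apoptosis genes (0.0218 and 0.0908) passed upward, and ribosomal protein genes (2.01e-08 and 0.327) passed downward, with the preset correlation alone.

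Cholesterol synthesis genes rose in 21 of 23 cases (21 adjusted over the list alone, adjusted p = 7.1e-19). Insig1, which senses sterols (chromosome 5, 28071363 to 28078662), was at 652 ± 1.22 against 33.5 ± 2.60 to 60.1 ± 8.16, and Cyp51 and Fdft1 rose by 3.56 ± 0.30 and 2.39 ± 0.20. TGF-beta response genes rose in 13 of 17 cases and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 5.75e-10), among them Tgif1 at 1503 ± 77.9 and Skil at 548 ± 4.94. Immediate-early and heat-shock genes, which also rise when tissue is dissociated, rose in 31 of 33 cases and fell in 1 (31 and 1 adjusted over the list alone, adjusted p = 8.94e-28). Fos (chromosome 12, 85473890 to 85477273) was at 6695 ± 1127 in IEL_Trm, 2.93 ± 4.14 in tTem, 0 in Tem and 4.49 ± 4.11 in Tcm. Nr4a1 (chromosome 15, 101254269 to 101274795), which is also a residency gene, was at 10319 ± 1189.8, Junb at 43521 ± 1612 and Dusp1 at 11040.2 ± 305.

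Lists of markers of other gut cells rose beside these groups, although 2 of 11 epithelial and 2 of 5 CD4 T cell markers are in another list. Intestinal epithelial markers rose in 8 of 11 cases (8 adjusted over the list alone, adjusted p = 0.000209), with Epcam at 81.0 ± 15.8 (37.2 ± 6.13 in Tem), Fabp2 at 21.7 ± 1.36 and Rbp2 at 18.7 ± 0.127. CD4 T cell markers rose in 4 of 5 cases and fell in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.00255, adjusted p = 0.0802 with an estimated correlation), with Cd4 at 88.3 ± 12.5. Gamma-delta T cell markers rose in 5 of 7 cases (5 up and 1 down adjusted over the list alone, adjusted p = 0.00518), with Tcrg-C2 at 577 ± 64.1, a segment whose reads are shared with its paralogs. Car2, a carbonic anhydrase gene, was at 1338 ± 96.4 in IEL_Trm and at 0 in tTem and Tem. Apol9b was at 408 ± 31.6 in IEL_Trm and at 0 in all 3 spleen groups, and Nr4a2, Osgin1, Spsb1 and Tspan9 were at 2735 ± 170.3, 2389 ± 252, 781 ± 78.4 and 391 ± 58.7. Il6ra and H2-Ob were listed at 0 in IEL_Trm, and S1pr5, Fbxl2, Prss12, Adamts14, Crip2 and Cmah were at 9.64 ± 13.6, 0.357 ± 0.505, 4.41 ± 0.170, 1.75 ± 1.56, 0.357 ± 0.505 and 10.9 ± 7.39.

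In all, 3146 genes differed, 1645 higher and 1501 lower (2213 and 1313 with voom), and 744 were higher and 565 lower against each of the 3 spleen groups. With a minimum log2 change of 1 the count was 1813, and it was 2036 without IEL_Trm library 1 (1004 higher and 1032 lower) and 1844 without IEL_Trm library 2.

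**Figure D3:**
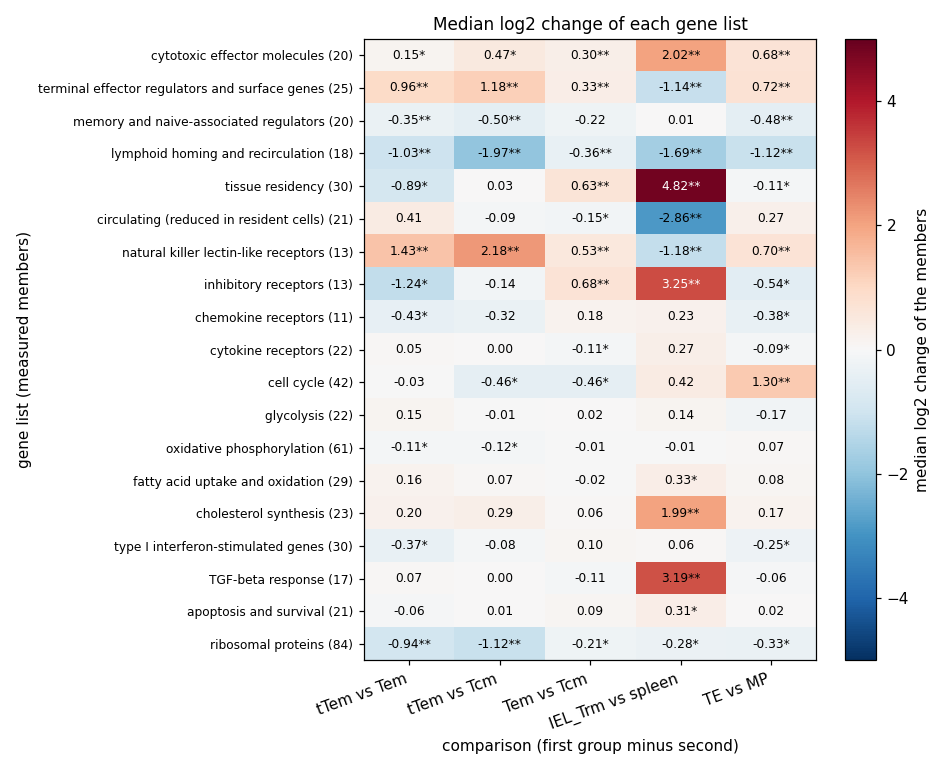
Median log2 change of the members of 19 gene lists in 5 comparisons, as a color scale. A star marks an adjusted p under 0.05 with the preset correlation and a pair of stars one that also passed with an estimated correlation, as for residency genes in IEL_Trm.

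The comparison of TE with MP set CD127lo KLRG1hi against CD127hi KLRG1lo cells at day 7. This gate also sorts on KLRG1, so it is not the gate that separates tTem from Tem. Klrg1 was at 3578 ± 181 in TE and 56.5 ± 5.64 in MP (5.96 ± 0.23, adjusted p = 1.36e-11). Gzma was at 21574 ± 2498 against 961 ± 212, Cx3cr1 rose by 3.68 ± 0.22 and Zeb2 by 3.56 ± 0.35. Tcf7, a regulator of memory precursors (chromosome 11, 52252371 to 52283014), fell from 2684 ± 420.5 in MP to 172 ± 26.7 in TE. Tnfsf8, which encodes the CD30 ligand (chromosome 4, 63831308 to 63861347), was at 201 ± 11.5 in MP and at 0 in TE, at least 87.1-fold lower by the bound of 3 reads per library.

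Terminal effector genes rose in 12 of 25 cases (16 adjusted over the list alone, adjusted p = 3.82e-21), and natural killer lectin-like receptors in 4 of 13 (8 adjusted over the list alone, adjusted p = 2e-09). Cytotoxic genes rose in 8 of 20 cases and fell in 3 (12 and 4 adjusted over the list alone, adjusted p = 2.76e-06), with Gzmk at 2710.1 ± 43.3 against 960.2 ± 21.5. Cell cycle genes rose in 7 of 42 cases (9 adjusted over the list alone, median 1.30, adjusted p = 2.19e-14), among them Mcm5 at 1295 ± 33.5 against 615 ± 126 and Cdc20 at 437 ± 18.1 against 122 ± 4.64. Homing genes fell in 9 of 18 cases and rose in 1 (10 and 1 adjusted over the list alone, adjusted p = 2.76e-11), and memory regulators fell in 6 of 20 (9 down and 1 up adjusted over the list alone, adjusted p = 3.67e-07). Id3 was at 4.29 ± 0.793 against 260.5 ± 24.4, and Bcl2 fell by 2.43 on the log2 scale. Ribosomal protein genes fell in 6 of 84 cases (33 adjusted over the list alone, adjusted p = 3.82e-21, adjusted p = 0.0884 with an estimated correlation). B cell markers fell in 1 of 10 cases (3 adjusted over the list alone, adjusted p = 0.0055), with adjusted p = 0.0512 with an estimated correlation. Natural killer cell markers (0.00892 and 0.0547) and replication-dependent histone genes (0.00123 and 0.0884) passed upward, and residency genes (0.0164 and 0.155), inhibitory receptors (0.0155 and 0.119), chemokine receptors (0.00295 and 0.0884), cytokine receptors (0.024 and 0.0884) and interferon-stimulated genes (0.000276 and 0.0512) passed downward, with the preset correlation alone.

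Ccr7 was at 12.2 ± 2.60 in TE against 513 ± 59.5 in MP, and Aff3 fell by 3.86 on the log2 scale. Cxcr5 and P2rx7 were at 2.64 ± 2.87 and 1.40 ± 1.98 in TE, against 166 ± 74.1 and 103 ± 0.653 in MP, and Nsg2 fell from 145 ± 19.0 in MP. Il7r, which encodes a marker of the gate, fell by 5.06 on the log2 scale. Kcnj8 and As3mt rose by 2.85 ± 0.39 and 2.44 ± 0.19. Esm1, Spag1, S1pr5 and Klre1 rose and Rgs10 fell, and each of these 5 calls ended without at least 1 library. Of 431 genes that differed, 157 were higher and 274 lower. The count was 82 in a fit of these groups alone (50 higher and 32 lower), 137 with day 7 and naive libraries alone, 265 with a minimum log2 change of 1 and 750.0 with voom (379 higher and 371 lower), so which direction held more genes depended on the method. It was 176 without MP library 1, 205 without MP library 2, 255 without TE library 1 and 199 without TE library 2.

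The contrasts of CD127lo with CD127hi cells at day 7 and day 55 were then set side by side, to ask whether the day 7 difference is seen again in memory. Day 7 cells were sorted on KLRG1 as well and day 55 cells on low CD62L as well, so day and gate change together. Earlier deposit changes with the day too, and Tem, unlike tTem, has no earlier deposit named. The shares that follow count the direction of change alone, whether or not a gene passed. Of 91 genes at least 2-fold higher in TE than in MP, 75 (82.4%) changed upward in tTem against Tem, 43 of them past the threshold (camera in limma, p = 6.36e-24, p = 8.23e-06 with an estimated correlation). Of 174 genes at least 2-fold higher in MP, 153 (87.9%) changed downward, 86 of them past the threshold (p = 2.94e-47, p = 3.41e-06 with an estimated correlation). Among all calls, 76 genes were higher in both contrasts against 5.05 expected by chance, and 128 were lower in both against 11.9 expected. The expected numbers treat the calls as independent. Both contrasts share 1 estimate of the spread of each gene, so these numbers may be too low. Both gates also sort on CD127, the product of Il7r. Across the 431 genes called at day 7, which are not independent replicates, Pearson's r of the changes was 0.771 and Spearman's rho 0.763. Over all 13549 genes r was 0.328 and rho 0.256. By direction alone, 68 of the 91 genes changed upward and 108 of the 174 downward in Tem against Tcm, with 8 and 3 past the threshold. In IEL_Trm against the spleen groups these were 36 of the 91 (39.6%) and 80 of the 174 (46.0%), with 15 and 46 past the threshold.

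**Figure D4:**
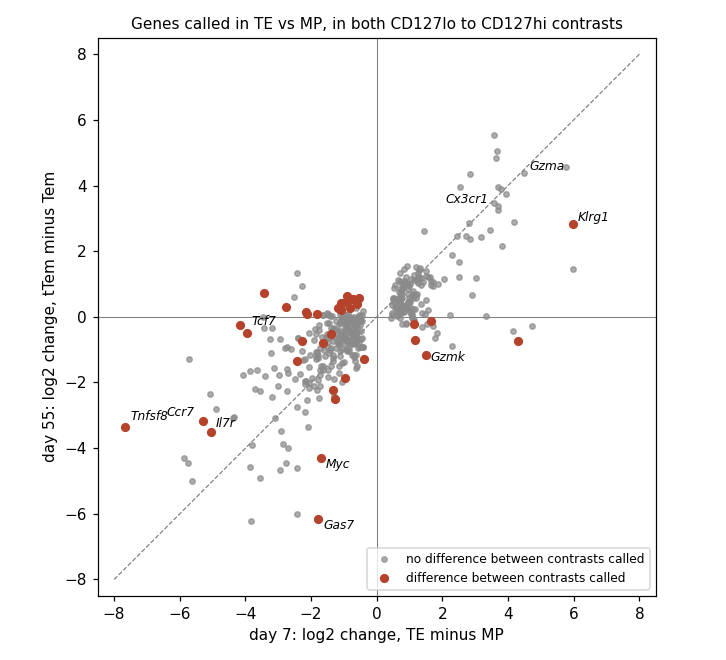
Log2 change of TE against MP at day 7 (x axis) and of tTem against Tem at day 55 (y axis) for the 431 genes called at day 7. Points are genes, and red marks those whose change differed between the contrasts, such as Tcf7 (-3.95 and -0.50).

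A test of the difference between the contrasts called 74 genes, with the day 55 change above the day 7 change for 36 of them and below it for 38 (39 and 27 with trimmed-mean scaling, 62 and 51 with voom). It cannot tell an effect of the day from one of the gate or of library origin, least of all for Klrg1, sorted on at day 7 alone. Tcf7 fell by 3.95 at day 7 and by 0.50 at day 55 (difference 3.46 ± 0.19, adjusted p = 2.50e-08). Plac8 (chromosome 5, 100553725 to 100572245) was at 211 ± 44.0 in tTem and 1442 ± 53.4 in Tem, but at 2227 ± 58.4 in TE and 2573 ± 271 in MP (difference -2.58 ± 0.20, adjusted p = 2.32e-06). Myc fell by 4.30 at day 55 and by 1.71 at day 7, and Klrg1 rose by 2.82 and 5.96. Gzmk was lower in tTem (220.5 ± 87.1 against 472 ± 32.4 in Tem) and higher in TE (2710.1 ± 43.3 against 960.2 ± 21.5 in MP). Of 84 ribosomal protein genes, 9 had a lower difference (63 adjusted over the list alone, adjusted p = 1.97e-44), with adjusted p = 0.0674 with an estimated correlation. The count was 16 in a fit of these groups alone, 120.0 with a pseudocount of 8, 36 without a filter, 113 with voom and 33 with convTem in place of Tem. It was 42 without tTem library 1, 35 and 37 without Tem library 1 or 2, 32 and 39 without MP library 1 or 2, and 31 without TE library 2.

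The comparison of tTem with TE set CD127lo cells of day 55 against those of day 7. Cell cycle genes fell in 41 of 42 cases (42 adjusted over the list alone, adjusted p = 1.09e-19, adjusted p = 0.0363 with an estimated correlation). Ccna2, a cyclin (chromosome 3, 36564865 to 36572150), was at 0.732 ± 1.04 in tTem and 956 ± 214 in TE. Kif11, a spindle motor (chromosome 19, 37376403 to 37421859), was at 0 in tTem and 406 ± 40.6 in TE, at least 197-fold lower. Bub1b and Shcbp1 were at least 169.7-fold and 121-fold lower, and Top2a and Ccnb2 fell by 7.28 and 8.39 on the log2 scale. Tpx2 and Ube2c were at 0.366 ± 0.518 and 0.320 ± 0.452 in tTem, against 446 ± 41.1 and 446 ± 46.7 in TE. Gzma was at 2899 ± 125 against 21574 ± 2498, Gzmb at 2404 ± 265 against 9182 ± 60.6 and Gzmk at 220.5 ± 87.1 against 2710.1 ± 43.3.

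Tcf7 was at 969.8 ± 94.6 in tTem and 172 ± 26.7 in TE, and Bcl2 rose by 2.31 ± 0.15. Ctsw, a protease gene of cytotoxic cells, rose by 1.64 ± 0.11. Inhibitory receptors fell in 8 of 13 cases and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0328, adjusted p = 0.382 with an estimated correlation), with Tigit at 27.3 ± 5.99 against 446 ± 76.9. Kcnj8, a potassium channel gene, was at 4213 ± 607 against 117 ± 7.49. The clock-controlled genes Nr1d1 and Tef were at 142 ± 30.5 and 552 ± 17.7 in tTem, against 3.64 ± 5.15 and 14.3 ± 4.81 in TE. Rab6b and Espn were at 162 ± 9.61 and 123 ± 3.59, against 1.87 ± 2.64 and 1.21 ± 1.72, and Prss12, Adgrg3, P2rx4 and Cxcr4 rose by 6.34, 5.05, 4.46 and 4.21 on the log2 scale.

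Ribosomal protein genes rose in 73 of 84 cases and fell in 2 (74 and 2 adjusted over the list alone, adjusted p = 3.19e-25, adjusted p = 0.382 with an estimated correlation). Mitochondrially encoded transcripts fell in 7 of 8 cases (7 adjusted over the list alone, adjusted p = 0.000249, adjusted p = 0.466 with an estimated correlation), with mt-Nd1 at 4758 ± 1677 against 15935 ± 2571. After removal of the trend on gene length and GC content, 61 ribosomal protein genes rose and 2 fell, with the median change going from 1.04 to 0.69. Of the mitochondrially encoded transcripts 5 then fell and 1 rose, with the median going from -1.66 to -0.67. Immediate-early and heat-shock genes (0.014 and 0.466) passed upward, with the preset correlation alone. Xist was at 618 ± 58.2 in tTem and 2.80 ± 3.96 in TE, while the Y-linked genes Eif2s3y, Ddx3y and Kdm5d were at 0 in tTem and at 588 ± 31.8, 400.3 ± 64.8 and 222 ± 5.22 in TE, at least 286-fold, 195-fold and 108-fold lower. A total of 5956 genes differed, 2964 higher and 2992 lower. Day and earlier deposit change together here, so their effects cannot be told apart.

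The comparison of Tcm with naive cells asked how memory cells differ from naive cells within the CD62Lhi gate. Ccl5, a chemokine of antigen-experienced cells (chromosome 11, 83525778 to 83530518), was at 43033 ± 1648 in Tcm and 5.09 ± 4.77 in naive cells (13.05 ± 0.33, adjusted p = 6.38e-15). S100a6 and S100a4 were at 4712 ± 44.4 and 761 ± 15.0, against 4.56 ± 4.02 and 0.529 ± 0.748. Tbx21, a regulator of effector genes, was at 1638 ± 326 against 5.82 ± 8.23. Itgax, Gzmk, Kcnj8 and Gzmb were at 0 in naive cells and at least 146-fold, 96.7-fold, 82.1-fold and 73.3-fold higher in Tcm. Igfbp4 fell from 1509 ± 181 in naive cells to 1.61 ± 0.0431 in Tcm.

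Terminal effector genes rose in 19 of 25 cases and fell in 2 (20 and 2 adjusted over the list alone, adjusted p = 6.28e-16), and cytotoxic genes rose in 15 of 20 (15 adjusted over the list alone, adjusted p = 3.3e-12). Chemokine receptors rose in 6 of 11 cases and fell in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.00808, adjusted p = 0.133 with an estimated correlation), with Cxcr3 at 3689 ± 482 against 52.6 ± 1.06 and Ccr9 at 14.4 ± 9.87 against 1279 ± 145. Memory and naive regulators fell in 10 of 20 cases and rose in 4 (10 and 4 adjusted over the list alone, adjusted p = 0.0236, adjusted p = 0.0807 with an estimated correlation), with Tcf7 at 1749 ± 76.9 against 4478 ± 79.7 and Lef1 at 984 ± 163 against 2891 ± 49.0. Oxidative phosphorylation genes rose in 48 of 61 cases and fell in 4 (50 and 4 adjusted over the list alone, adjusted p = 3.65e-15). With an estimated correlation they passed only narrowly (camera, adjusted p = 0.0494). Among them Cox6b1 was at 1347 ± 74.8 against 228 ± 39.9. After removal of the trend on gene length and GC content 38 of 60 rose and 0 fell, and the median change went from 1.04 to 0.58. Glycolysis genes rose in 15 of 22 cases and fell in 1 (15 and 1 adjusted over the list alone, adjusted p = 2.62e-05, adjusted p = 0.0807 with an estimated correlation), and in 10 of 21 after that removal, with the median going from 0.90 to 0.65. Natural killer lectin-like receptors (0.000539 and 0.0765), inhibitory receptors (0.0169 and 0.133), cytokine receptors (0.0123 and 0.0807), cell cycle genes (0.00733 and 0.284), replication-dependent histone genes (0.0111 and 0.152), myeloid markers (0.0253 and 0.1) and natural killer cell markers (0.00255 and 0.0581) passed upward, and cholesterol synthesis genes (0.0318 and 0.309) passed downward, with the preset correlation alone. Of these, histone genes and myeloid markers no longer passed after removal of the length and GC trend (camera, adjusted p = 0.0647 and 0.0855).

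Ribosomal protein genes rose in 78 of 84 cases and fell in 1 (78 and 2 adjusted over the list alone, adjusted p = 5.12e-32, adjusted p = 0.0765 with an estimated correlation). All 8 mitochondrially encoded transcripts fell (8 adjusted over the list alone, adjusted p = 1.96e-06, adjusted p = 0.133 with an estimated correlation). After removal of the length and GC trend 66 of the ribosomal protein genes rose and 1 fell (median from 1.40 to 0.89), and 6 of the 8 mitochondrially encoded transcripts fell (median from -2.22 to -1.07). Slamf7 was at 479 ± 76.1 against 3.97 ± 4.12, Samd3 rose from 0.860 ± 1.22 in naive cells, and St6gal1, Ramp1 and Atp1b1 fell by 7.48, 7.04 and 6.88 on the log2 scale. Dntt, which adds bases at receptor gene junctions, and Kcna2 were at 0 in Tcm and at least 62.0-fold and 77.6-fold lower. Xist was at 1197 ± 71.9 against 3.44 ± 4.86, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 0 in Tcm and at least 278-fold, 262-fold, 137-fold and 98.4-fold lower. In all, 5915 genes differed, 3026 higher and 2889 lower (2417 and 2797 with voom). Among the 13218 genes with known length and GC content, 5819 differed before and 3655 after removal of the trend on these, 2922 of them both times. Earlier deposit and cell state cannot be told apart.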

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

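The test of the difference between the day 55 and day 7 contrasts was planned, and the bounds for the tests of scaling and of gene length and expression level were set before their results were seen. The comparison of tTem with convTem for the ribosomal protein genes was chosen after the result was seen.

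The change of CD127lo against CD127hi cells differed between day 55 (tTem against Tem) and day 7 (TE against MP) for 74 genes, by a limma test of the difference itself. Day 7 cells were also sorted on KLRG1 and day 55 cells on low CD62L. Earlier deposit and donor sex, by Xist and Y-linked genes, also change with the day, and Tem, unlike tTem, has no earlier deposit named. The test therefore cannot tell an effect of the day from one of the gate or of library origin. With convTem, from the same earlier deposit as tTem, in place of Tem, 33 genes were called, 29 of them among the 74. Each of the genes below was picked out by that test, and each value is the day 55 log2 change minus the day 7 log2 change. Among genes with a higher change at day 55, Tcf7 differed by 3.46 (-0.50 at day 55 and -3.95 at day 7), Tnfrsf25 by 2.22 (0.10 and -2.12), Ccr7 by 2.14 (-3.16 and -5.30) and Armc7 by 1.79 (1.40 and -0.40). Tef differed by 3.26 (2.20 and -1.07), P2rx4 by 3.06 (0.29 and -2.77), Rab6b by 4.18 (0.74 and -3.44), Espn by 3.92 (-0.24 and -4.16) and Mgrn1 by 1.89 (0.07 and -1.82). Tnfsf8 differed by 4.31 (-3.35 and -7.66), a fitted value that depends on the pseudocount because both TE libraries were at 0.

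Among genes with a lower change at day 55, Plac8 differed by -2.58 (-2.78 at day 55 and -0.20 at day 7), Adam19 by -2.38 (-2.56 and -0.18), Tigit by -2.04 (-2.20 and -0.16) and Myc by -2.60 (-4.30 and -1.71). Klrg1 differed by -3.15 (2.82 and 5.96) and Gas7 by -4.38 (-6.17 and -1.78). The signs were opposite for Gzmk at -2.65 (-1.15 at day 55), Itgax at -2.70 (-2.30 and 0.40), Uhrf1 at -3.98 (-2.67 and 1.32) and Pmf1 at -1.85 (-0.70 and 1.15). With 1 of the 8 libraries left out in turn, the calls of Mgrn1, Uhrf1 and Tigit each ended 7 times, that of Espn 4 times, and those of Rab6b, P2rx4 and Pmf1 each 2 times. The highest adjusted p was 0.252 for Mgrn1 (without TE library 2), 0.222 for Uhrf1 (without TE library 2) and 0.187 for Tigit (without MP library 2).

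The same test on gene lists picked out 4 lists with the preset correlation between genes. The median difference was 0.31 for cytokine receptors (medians of 0.05 at day 55 and -0.09 at day 7, adjusted p = 0.000743), -0.23 for oxidative phosphorylation (-0.11 and 0.07, adjusted p = 0.000743) and -0.62 for ribosomal proteins (-0.94 and -0.33, adjusted p = 1.97e-44). It was -1.54 for cell cycle genes (-0.03 and 1.30, adjusted p = 4.18e-12), a value that depends on the pseudocount because some members sit at 0 at day 55. None of the 4 passed with an estimated correlation (adjusted p = 0.0674 for cytokine receptors, cell cycle and ribosomal proteins, and 0.386 for oxidative phosphorylation).

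The ribosomal protein genes, which fell in tTem against Tem, were weighed further. Their median change was -0.94. The central part of 10000 random lists matched on expression and exonic length spanned -0.0886 to 0.0924, and 0 were as low. This argues against expression level and annotated exonic length. That length joins the exons of all annotated transcripts and can exceed that of the transcripts present, so an effect of transcript length stays open. GC content was not matched, but after removal of a trend on exonic length and GC content the median was -0.88. Against convTem, from the same earlier deposit as tTem, the median change was -0.64, which argues against the origin of the Tem libraries as the whole cause. With trimmed-mean scaling it was -0.92, but this scaling moved the median of all genes by only 0.0125 and so does not test scaling, which stays open for the level itself. A change of scale moves ribosomal and matched genes alike, so the gap between them does not rest on it. Reads shared with processed pseudogenes were not tested and stay open, and so does a biological difference between CD127lo and CD127hi memory cells.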

How the results depend on the processing

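Voom on the recovered reads, removal of a trend on gene length and GC content, autosomal genes only, scaling without ribosomal RNA and mitochondrial features, convTem in place of Tem in the difference between days, and the replicate number as a block in the day 7 and naive libraries alone were chosen after seeing the data. The planned count models were not run, because the table holds normalized values. Counts below are of genes past the threshold, and the cause of a change was not tested unless given. Fitting only the groups compared, which leaves fewer libraries to estimate the spread, gave 193 genes for tTem against Tem, 416 for tTem against Tcm, 82 for TE against MP and 16 for the difference between days. It gave 0 with limma for Tem against Tcm, convTem against tTem and convTem against Tem, with 1122, 1589 and 1019 at an unadjusted p under 0.05. A minimum log2 change of 1, stricter by construction, gave 566, 808, 1813 (IEL_Trm against spleen memory), 265 and 164 (convTem against tTem) in place of 1023, 1349, 3146, 431 and 301. For TE against MP, voom gave 750.0 (379 higher and 371 lower) and the libraries of the same earlier set 137, and the balance of 157 higher and 274 lower also turned to 50 and 32 in the fit of these groups alone. For the difference between days, pseudocount 8 gave 120.0, no filter 36, voom 113 and convTem in place of Tem 33. Among 13218 genes with known length and GC content, Tcm against naive fell from 5819 to 3655 after removal of the trend on these, with 2922 called both times. That removal also reversed mt-Nd4 in IEL_Trm (0.0797), Cd69 (0.66), Klrc1 (0.15) and Nkg7 (-0.17) in tTem against TE, and Cst3 in Tcm against naive (-0.0910). With an estimated correlation, 45 of 112 list calls passed. With 1 library left out, counts ran from 526 to 764 for tTem against Tem (526 without tTem library 1 or Tem library 1, 640.0 without Tem library 2), 736 to 978 for tTem against Tcm (796 without tTem library 1, 795 and 736 without Tcm library 1 or 2), and 18 to 35 for Tem against Tcm (18 without Tcm library 2, 24 and 23 without Tem library 1 or 2). They ran from 1844 to 3073 for IEL_Trm (2036 and 1844 without IEL_Trm library 1 or 2), 176 to 255 for TE against MP (176 and 205 without MP library 1 or 2, 255 and 199 without TE library 1 or 2), 4395 to 4789 for tTem against TE and 4632 to 4956 for Tcm against naive. They ran from 92 to 218 for convTem against tTem (134 without tTem library 1, 92 and 115 without convTem library 1 or 2), 2 to 7 for convTem against Tem (2 without either convTem library, 7 and 4 without Tem library 1 or 2), and 31 to 81 for the difference between days (42 without tTem library 1, 35 and 37 without Tem library 1 or 2, 32 and 39 without MP library 1 or 2, 31 without TE library 2). The lone library left in a group is then assumed to vary like the other groups. The replicate number as a block gave 1001 for tTem against Tem and 54 for the difference between days. After group means were removed, libraries of the same number correlated between -0.0491 and 0.0847 over 28 pairs of groups, and 10 of 16 libraries correlated best with a library of their own number. The highest values were for MP and TE (0.0847), TE and naive (0.0744) and MP and naive (0.0332). In each of these 3 groups library 1 had more mt-Co1 and a smaller share of CT010467.1 than library 2, so a technical difference shared by number stays open there. The number as a block in the day 7 and naive libraries alone gave 491 for TE against MP, 5524 for tTem against TE, 5504 for Tcm against naive and 108 for the difference between days. For 646 values of named genes, 9956 of 10922 alternatives kept direction and side of the threshold, 961 kept direction only and 5 reversed. Depth limits genes near the filter most in naive library 2 (2339149 reads), where 3 reads equal 5.16 normalized reads, and the simulated data showed 50% recovery of 2-fold changes for tTem against Tem.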

Other observations

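All 28 pairs of groups were compared, with counts from 17 (convTem and Tem) to 6931 (IEL_Trm and naive). Within the spleen at day 55, convTem and Tcm differed in 183 genes. At day 7, MP differed from naive cells in 3598 genes and TE in 4789. IEL_Trm differed from tTem in 2828, from Tcm in 2599, from convTem in 2454 and from Tem in 2435 genes. The day 7 signatures were also seen against convTem, where 79 of 91 genes of TE (86.8%) changed upward and 156 of 174 genes of MP (89.7%) downward in tTem by direction alone, with 12 and 59 past the threshold.

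Immunoglobulin transcripts differed across groups sorted as T cells. Ighm was at 353 ± 1.98 in tTem, 775 ± 145 in Tcm, 1096 ± 11.8 in Tem, 804 ± 142 in convTem, 934 ± 99.3 in IEL_Trm, 708 ± 36.4 in TE, 2221 ± 257 in MP and 3222 ± 42.2 in naive cells. Of 10 measured B cell markers, 0 are in another list and 4 reach 10 normalized reads in spleen memory cells. Other marker lists do share members with another list, namely 5 of 8 natural killer cell, 2 of 6 myeloid, 2 of 5 CD4 T cell and 2 of 11 epithelial markers, but 0 of 7 gamma-delta T cell markers. A change of those that share members need not come from other cells. Of 11 epithelial markers, 10 reach it in IEL_Trm and 3 in spleen memory cells. The ribosomal RNA locus CT010467.1 took 10.7% to 13.7% of reads in day 55 libraries and 2.59% to 4.79% in day 7 and naive libraries, except 11.8% in naive library 2.

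The tests of autosomal genes, of the trend on gene length and GC content, of the shares over all genes called in tTem against Tem, and of whether the Tem libraries explain the place of convTem were chosen after the data or the result were seen.

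Many genes differed between day 55 libraries and day 7 or naive libraries. On autosomes 5660.0 genes differed between tTem and TE and 5579 between Tcm and naive cells. Since 12804 of the 13549 genes tested lie there and donor sex can act on them too, these counts decide nothing, and donor sex and cell state cannot be told apart. Across genes, which are not independent replicates, the changes of tTem against TE and of Tcm against naive cells had Pearson's r = 0.362 (Spearman's rho 0.475). This r lies between the bounds set for and against a shared effect of the earlier deposits. Of 3578 genes called in both comparisons, 3285 (91.8%) changed in the same direction, which a shared effect of the deposits could give. That effect, donor sex and biology cannot be told apart. After removal of a trend on gene length and GC content, 4132 and 3655 genes differed, in place of 5865 and 5819 of the genes with known length. Only 3176 and 2922 genes were called both before and after, so the removal changed which genes were called as well as how many. Since the trend follows the deposits, a share of these differences may come from library preparation or from biology.

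For most genes called in tTem against Tem, convTem lay between Tem and tTem (414 of 436 higher and 553 of 587 lower genes). Some genes called between convTem and Tem lay beyond tTem, such as Nr4a1 (3.80 in convTem and 3.14 in tTem, both against Tem) and Cd200r1 (-3.81 and -1.62). Others lay between, such as Gzma (2.62 and 4.37). The shares below do not cover genes that were not called in tTem against Tem. Among genes called both in tTem against Tem and in TE against MP, it showed on the linear scale a median share of 0.324 of the difference for 77 genes higher in tTem and of 0.386 for 129 genes lower in tTem. These medians differ by -0.0619 (bootstrap interval -0.102 to -0.0222). Over all genes called in tTem against Tem they were 0.368 (436 genes) and 0.383 (587 genes), which differ by -0.0146 (-0.0450 to 0.0172). Both differences lie within the range set for a mixture of CD127lo and CD127hi cells. By its label the convTem gate has no CD127 part, so CD127lo and CD127hi cells both fall within it. The genes were chosen for a difference between tTem and Tem, so intermediate cells within that gate could give such shares too. The test does not tell such cells from a mixture. The first interval, which treats genes as independent, leaves out the equal shares of a mixture. Over all genes called in tTem against Tem, quartiles of the share were 0.259 and 0.509 (higher) and 0.272 and 0.496 (lower). A population of intermediate cells was not tested and stays open. Of 17 genes called between convTem and Tem, 76.5% moved the way tTem differs from Tcm, which lies between the bounds set, so an effect of the other origin of the Tem libraries cannot be told apart.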
